A study of Mus musculus with 2 samples.

How the data were processed

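Gene expression was measured by RNA sequencing in mouse embryonic neural cells of the CD-1 strain. Per the labels' protocols, a control plasmid or an Rbm3 knockdown plasmid was electroporated into the cortex in utero at embryonic day 13. The dams were made hypothermic at embryonic day 14, and GFP-positive cells, those that had taken up plasmid, were sorted by flow cytometry at embryonic day 15. Per the labels' protocols, 100 ng of total RNA went into each library, mRNA was enriched with oligo(dT) beads and fragmented, and cDNA was primed with random hexamers. Each group had 1 library, so the design has 2 libraries and no replicate.

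Tools named in the submitters' processing notes are TopHat2 2.0.12, Bowtie 1.0.1 and HTSeq 0.6.0, with no role stated for any of them. The genome build, the gene annotation and whether counting used strand are not given in the sources used here. The deposited table lists 15643 Ensembl genes. For each library it holds raw read counts per gene, per the file headers and the whole-number values. It also holds RPKM values (reads per kilobase of gene, scaled to library depth), per the file headers. The ratio of reads to RPKM between both libraries was a single constant over the genes listed. The authors' deposited columns of log2 fold change and log2 average CPM, and their p-value and adjusted p-value (FDR), complete the table, per the file headers.

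Only genes above a low minimum are listed. A gene with under 10 reads in the knockdown library had at least 18 in the control library, and one with under 10 in the control library had at least 17 in the knockdown library. The column totals are therefore totals over listed genes, 17757555 reads in the control library and 16823612 in the knockdown library, and library depths are at least this large. The test behind the authors' p-values is not stated. After several preset dispersions had been tried on the data, edgeR's exact test on TMM-scaled counts with a dispersion of 0.1 for each gene gave the deposited p-values to within 4.55e-15 and the deposited log2 fold changes to within 4.8e-14. The FDR column was the Benjamini-Hochberg adjustment of those p-values. With 1 library per group the spread between replicates was thus assumed in these p-values, not measured. They compare 2 libraries, not the conditions.

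The comparison used the deposited read counts. Library totals were scaled with TMM factors from edgeR 4.0.16 (1.04 for the control and 0.963 for the knockdown library), which treat the bulk of genes as equal between libraries. The log2 ratio of knockdown over control was taken on CPM with a pseudocount of 0.5 CPM, which understates the difference for genes with few reads. Genes with a mean of at least 5 CPM over the 2 libraries, 12140 in number, were called measured. A measured gene was called higher at a log2 ratio of at least 1 and lower at -1 or below, as a rule of size. No p-value was computed across genes, since genes are not replicates. Ratios of single genes carry exact (Clopper-Pearson) 95% intervals from the split of reads between the libraries, without the pseudocount. List medians under an alternative were set against an interval from resampled (Poisson) counts. These intervals cover counting error only, and PCR copies make even that an underestimate. Where a library had 0 reads, the fold was computed against a floor of 3 reads in that library.

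Before the data were examined, 30 gene lists were fixed: pathways, neural cell types, other cell types that the sort might hold, cell cycle phases and stress responses. Each list's median log2 ratio was placed among the medians of 10000 random lists of the same size, drawn from measured genes in the same of 20 bins of mean CPM. That percentile describes these 2 libraries and is not a p-value. Also fixed then was the rule for naming genes: Rbm3, Cirbp and Yap1, the 12 highest and 12 lowest log2 ratios among genes with a mean of at least 10 CPM (predicted genes left out), members of the Hippo list, and up to 4 members of each list with the largest log2 ratios, or the 2 most abundant where no member reached 2-fold. Ctgf, Fn1, Sox2, Pax6, Sox9, Eomes, Neurod2, Uty and Erdr1 fall outside this rule and were chosen after their values were seen. Some genes that the rule takes are not reported here. Alternatives fixed then were 3 other scalings, 2 other pseudocounts, 3 other CPM minimums, 2 other fold thresholds and the authors' log2 fold change. A correction for transcript length, other dispersions for the authors' test and 4 further lists were chosen after the data were seen. The length came from reads per RPKM and the correction was a lowess curve with a span of 0.3.

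Gene names were those of the table. A total of 23 names that a spreadsheet had turned into dates were restored from the Ensembl gene ID. Positions of Rbm3, Cirbp and Yap1 were looked up by gene ID in GENCODE M21 (GRCm38), in which 15459 of the listed IDs were found. The calculation was tested on simulated data for the 12140 measured genes of this comparison. With counting error only, 0 of 11940 unchanged genes passed 2-fold and the 50 genes simulated as 4-fold higher had a median log2 ratio of 1.98. With a dispersion of 0.1, the value behind the authors' p-values, 12.4% of unchanged genes passed 2-fold. Of 200 simulated unchanged lists of 20 genes, 11 with counting error only and 3 with a dispersion of 0.1 fell outside the central 95% of random lists. Software was R 4.3.3, DESeq2 1.42.0 for its size factors, and Python 3.11.15 with numpy, pandas, scipy, statsmodels and matplotlib.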

Results

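RNA-seq profiles of GFP-positive cells sorted from cooled mouse embryonic cortex were compared between an Rbm3 knockdown plasmid and a control plasmid. Rbm3 is a cold-inducible RNA-binding protein, and the series asks how it acts in cortical development under maternal hypothermia, with Yap1 named in its title. Each group had 1 library. The control library held 17757555 reads over the listed genes and the knockdown library 16823612, with medians of 468 and 385 reads per gene. Reads were spread over 15637 genes in the control library and 15582 in the knockdown library, and the 10 most abundant genes took 4.38% and 3.20% of reads. With no replicate, each difference below is a difference between 2 libraries. Its counting interval says nothing about the spread between embryos, litters or sorts.

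The targeted gene, Rbm3 (ENSMUSG00000031167.10, chromosome X, 8138975 to 8145880, minus strand, GRCm38), differed little between the libraries. It had 3242 reads (176 CPM) in the control and 2397 (148 CPM) in the knockdown library. The knockdown library thus held 84.1% of the control level (95% counting interval 79.8% to 88.7%), a log2 ratio of -0.25. Across other scalings and pseudocounts, the length correction and the authors' value, the log2 ratio ranged from -0.36 to -0.23. In the authors' deposited table, Rbm3 had a log2 fold change of -0.25 with a p-value of 0.704. The interquartile range of log2 ratios over measured genes was -0.30 to 0.32, and Rbm3 lay inside it under the TMM scaling. Another scaling moves Rbm3 and the other genes together: with library totals the median of measured genes went from 0.03 to -0.07. Cirbp (ENSMUSG00000045193.7, chromosome 10, 80165985 to 80172786), the other cold-inducible RNA-binding protein examined, had 253 CPM in the control and 282 CPM in the knockdown library, a log2 ratio of 0.15. The median of both genes was -0.05. The library labelled knockdown is so called below on the strength of its label.

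Yap1 (ENSMUSG00000053110.7, chromosome 9, 7931999 to 8004596, minus strand, GRCm38), the transcriptional coactivator at the end of the Hippo pathway, was lower in the library labelled knockdown. It had 1086 reads (58.9 CPM) in the control and 473 (29.2 CPM) in the knockdown library, 2.02-fold lower (95% counting interval 1.81 to 2.25). Its paralog Wwtr1, which encodes TAZ, was 1.70-fold lower (1.51 to 1.90), and Stk3, one of the upstream kinases, was 1.60-fold lower (1.31 to 1.96). The pathway went both ways, with 15 of its measured genes above a log2 ratio of 0 and 8 below, among them Nf2 at -0.21 and Wwc2 at -0.27. Of 23 measured Hippo genes, Yap1 was the 1 past 2-fold lower, Wwc1 (2.08-fold higher, 1.97 to 2.19) the 1 past 2-fold higher, and 21 lay between. Tead2, the most abundant TEAD partner of Yap1, had 113 and 114 CPM, and the kinase Lats1 had a log2 ratio of 0.59. Dchs1 and Fat4, protocadherins upstream of the pathway, had log2 ratios of 0.85 and 0.55. The list median was 0.29, at percentile 98.3 of random lists, and 93.1 after the length correction. Yap1 sat at the 2-fold line: its log2 ratio was -0.98 with median-of-ratios scaling and -1.11 with library totals. In the authors' deposited table its log2 fold change was -1.01 with a p-value of 0.129 and an FDR of 0.995, so it was not among their calls.

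Genes that YAP and TAZ are known to activate through TEAD factors were split. Of 18 measured targets, 3 were lower, 1 was higher and 14 lay between, and the median log2 ratio was -0.01 (percentile 58.8). Ptpn14 was 2.94-fold lower (2.23 to 3.92), Foxf2 2.60-fold lower (1.98 to 3.45) and Ccdc80 2.36-fold lower (1.97 to 2.84). Cyr61, which encodes a secreted matrix protein and is a widely used YAP readout, was 2.40-fold higher (2.11 to 2.73). Ctgf, the other common readout, had 150 and 69 reads, a log2 ratio of -0.86, and Amotl2 had a log2 ratio of 0.44. The median was 0.003 with median-of-ratios scaling and 0.14 with a minimum of 20 CPM, so the list had no direction of its own. Other sets differed far more between these libraries, with medians of 1.58 for immediate early and -3.78 for meningeal fibroblast genes. Target levels were not separated from those differences, so the list is no measure of YAP activity here.

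Over the transcriptome, 259 of 12140 measured genes were higher and 547 lower in the library labelled knockdown, and 11334 lay between. These were 2.13% and 4.51% of measured genes. In the simulation with a dispersion of 0.1, 12.4% of unchanged genes passed 2-fold, so the counts are no larger than that assumed spread would give. That spread was not measured here, so the simulation cannot tell which differences exceed the spread between replicates. The median log2 ratio of measured genes was 0.03. Scaling by library totals shifted that median by -0.11, and 187 genes were then higher and 693 lower. With upper-quartile factors the counts were 194 and 672. The authors' deposited table held 1231 genes at their stated threshold (p below 0.05 and a log2 fold change above 1 in size), 285 higher and 946 lower. At an FDR below 0.05 it held 294, of which 42 were higher and 252 lower. Medians of 18 of the 30 gene lists lay outside the central 95% of random lists, 7 above and 11 below. Members of a list can vary together and some lists share genes, so no rate for unchanged lists can be set beside this count.

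**Figure D1:**
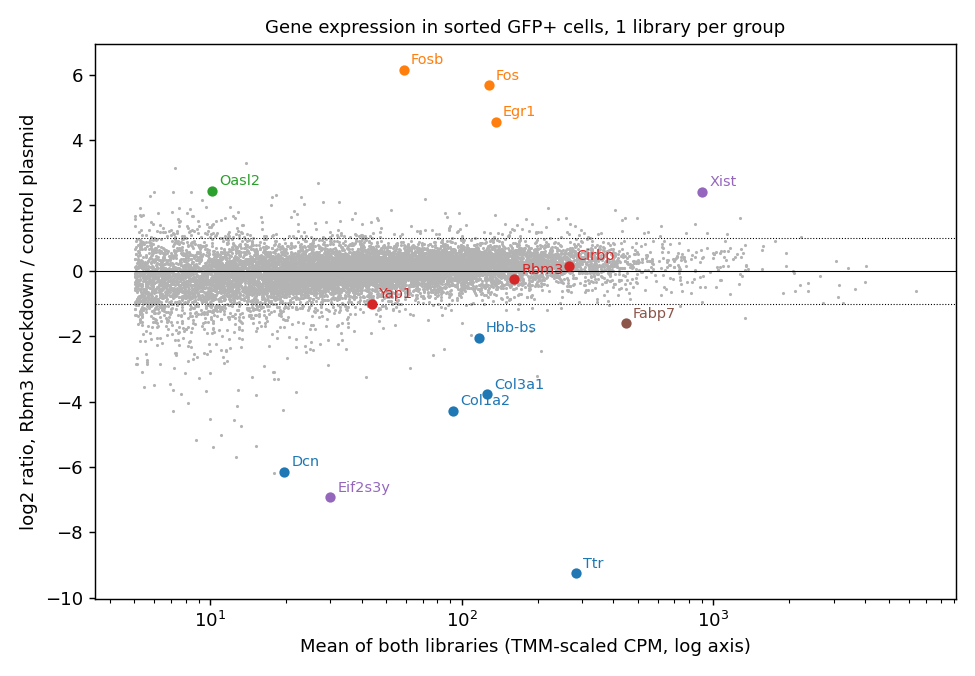
Each point is 1 of the 12140 measured genes, with its mean TMM-scaled CPM over both libraries on a log axis and its log2 ratio of Rbm3 knockdown over control plasmid, and dotted lines at a log2 ratio of 1 and -1. Rbm3 (-0.25) and Cirbp (0.15) lie in the bulk of genes and Yap1 on the lower dotted line, while Ttr (-9.25) and Fosb (6.16) are among the points farthest from 0.

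Genes of tissues next to the cortex were among those with the lowest ratios, with genes of the Y chromosome and a globin gene. Ttr, the transthyretin transcript typical of choroid plexus, had 10451 reads in the control and 7 in the knockdown library, 1312-fold lower (637 to 3264). Other choroid plexus genes were lower too: the chloride channel gene Clic6 by 52.9-fold (24.1 to 145), the potassium channel subunit Kcne2 by 24.4-fold (11.6 to 61.4) and the water channel Aqp1 by 11.9-fold (7.56 to 19.8). Of 5 measured choroid plexus genes, 4 were lower, with a median of -3.56 that ranged from -4.96 to -2.37 over the alternatives. Of 11 measured meningeal fibroblast genes, 10 were lower, with a median of -3.78 (-4.20 to -2.83). The proteoglycan genes Dcn, with 724 and 1 reads (a ratio of 0.00157, 3.97e-05 to 0.00879), and Lum (56.7-fold lower, 21.9 to 210), the collagen gene Col1a2 (20.5-fold lower, 17.3 to 24.5) and the transporter Slc6a13 (122-fold lower, 47.5 to 451) led this list. Both medians were below each of 10000 random lists. The meningeal exception was fibronectin, Fn1, with a log2 ratio of -0.14.

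Blood and vessel genes were lower by less. Of 11 measured endothelial genes 8 were lower, with a median of -1.67 (-1.78 to -1.08 over the alternatives), led by Egfl7 (5.50-fold lower, 4.23 to 7.24), Ramp2 (4.47-fold, 3.50 to 5.79) and Eng (4.23-fold, 3.49 to 5.17). Pericyte and mural genes had 3 of 8 lower and a median of -0.75, with Vtn 4.83-fold lower (4.12 to 5.70) and Acta2 5.40-fold lower (3.61 to 8.36). Erythroid genes had 6 of 7 lower and a median of -2.04. Among these, the adult beta-globin gene Hbb-bs was 4.15-fold lower (3.83 to 4.50) and Hbb-bt 52.5-fold lower (26.4 to 122), though near-identical globin copies can trade reads. Microglia and macrophage genes did not move together: 3 were higher, 1 lower and 8 between, with a median of 0.12. The mannose receptor Mrc1, found on macrophages at vessels and meninges, was 5.25-fold lower (4.19 to 6.65), while the lysozyme gene Lyz2 was 3.68-fold higher (3.09 to 4.40) and Ptprc, which encodes CD45, 3.66-fold higher (2.57 to 5.30). Lyve1, also a marker of such macrophages and of lymphatic vessels, had 378 reads in the control and 0 in the knockdown library, at least 110.7-fold lower at a floor of 3 reads. The remaining lowest genes by the naming rule were Slc22a6, Cldn11, Col6a1 and genes of the Y chromosome.

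The libraries differed in sex-linked transcripts. Eif2s3y, Ddx3y and Kdm5d, genes of the Y chromosome, had 1104, 664 and 467 reads in the control library and 0 in the knockdown library. Eif2s3y was at least 323-fold lower, Ddx3y at least 194-fold and Kdm5d at least 136.79-fold at a floor of 3 reads. Of 5 listed genes placed on the Y chromosome, Uty also had 323 and 0 reads. Erdr1 had 600 and 772, so its reads do not follow those of the others and are not read here as Y-chromosome transcripts. Xist, the RNA of the inactive X chromosome, had 5246 reads in the control and 24642 in the knockdown library, 5.35-fold higher (5.19 to 5.51). Tsix, its antisense partner, was 6.84-fold higher (5.66 to 8.32), but whether counting separated the strands is not stated, so the 2 cannot be told apart here. The labels give no sex. The control library held cells of male embryos, since Y-chromosome genes other than Erdr1 had reads there. Its 5246 Xist reads (285 CPM) point to cells of female embryos as well, so it is not read as male only. The Y-chromosome genes other than Erdr1 had 0 reads in the knockdown library, so the libraries differed in their mix of embryo sexes.

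Immediate early genes, transcription factors induced within minutes of a stimulus, had the highest ratios. Fosb was 102-fold higher (66.7 to 166), with 21 and 1887 reads, Fos 57.2-fold higher (45.9 to 72.1) and Egr1 24.6-fold higher (21.3 to 28.6). Of 15 measured members of the list 13 were higher and 0 lower, with a median of 1.58, above each of the random lists. Junb had a log2 ratio of 2.06. Heat shock genes had a median of -0.01, with 0 of 9 past 2-fold in either direction, and Hsp90ab1, the most abundant, had a log2 ratio of -0.15. The unfolded protein and integrated stress response list had a median of -0.08 and p53 targets one of -0.02, with 0 members past 2-fold in both. Plk2 had a log2 ratio of -0.35 and Mdm2 one of 0.55. The heat shock median was 0.0061 with median-of-ratios scaling and the p53 median 0.21 with no CPM minimum, so neither had a direction.

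Interferon-stimulated genes were also higher in the library labelled knockdown. Of 11 measured genes 7 were higher, 0 lower and 4 between, with a median of 1.30, again above each random list, and of 0.82 with a minimum of 20 CPM. Oasl2, an antiviral oligoadenylate synthetase-like gene, was 6.24-fold higher (4.63 to 8.55). The interferon feedback protease Usp18 was 6.47-fold higher (4.50 to 9.55) and the transcription factor Irf7 3.76-fold higher (2.82 to 5.06). Counts were low in the control library, with 52 reads for Oasl2 and 35 for Usp18. Trim25 and Rnf213, which are interferon-inducible as well, were 5.05-fold (4.20 to 6.11) and 4.47-fold (3.81 to 5.27) higher. Also among the 12 highest were Saa3, an acute phase gene (11.8-fold, 8.52 to 16.8), Adamtsl3 and Tgfbi. The microglia list median was 0.12 beside these values.

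**Figure D2:**
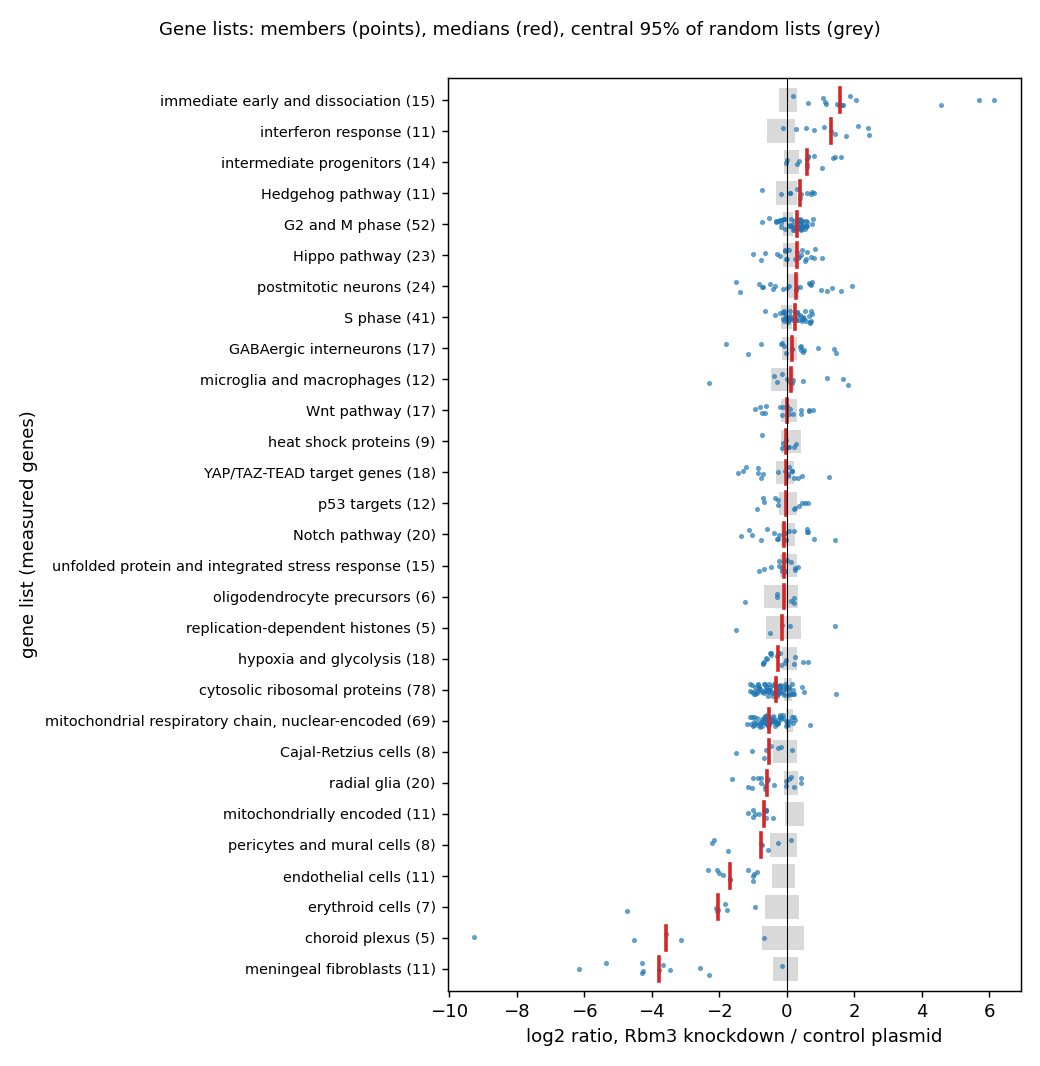
Each row is 1 gene list with its number of measured genes, and points are the log2 ratios of its members (knockdown over control), red bars the list medians and grey boxes the central 95% of 10000 random lists matched on mean CPM. Immediate early (1.58) and interferon (1.30) medians lie to the right of their boxes, and those of meningeal (-3.78), choroid plexus (-3.56), erythroid (-2.04) and endothelial (-1.67) genes to the left.

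Among neural cell types, radial glial genes as a set had a median below 0 and intermediate progenitor genes one above 0 in the library labelled knockdown, with most members of both within 2-fold. Radial glia are the stem cells of the cortex, and 15 of 20 of their markers had a log2 ratio below 0. The median was -0.58, below each random list, with 3 genes past 2-fold. Fabp7, a lipid-binding protein of radial glia, was 3.05-fold lower (2.94 to 3.17), the intermediate filament Nes 2.20-fold (2.10 to 2.30) and the Notch effector Hes5 2.06-fold (1.81 to 2.36). The core transcription factors of these cells differed less, with log2 ratios of 0.13 for Sox2, -0.37 for Pax6 and -0.01 for Sox9. Intermediate progenitors, the dividing cells between radial glia and neurons, had 4 of 14 markers higher, 0 lower and a median of 0.62, above each random list. Insm1 had a log2 ratio of 1.60, the Notch ligand Dll3 was 2.75-fold higher (2.44 to 3.10) and Sstr2 2.59-fold higher (2.40 to 2.80). Eomes, which encodes the defining factor Tbr2, had a log2 ratio of 0.59. Beside these differences, the control library carried the meningeal and choroid plexus reads described above.

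Neuronal genes went both ways. Of 24 measured, 5 were higher and 2 lower, and the median of 0.28 lay at percentile 79.0 of random lists. Neurod2, a transcription factor of projection neurons, was on the high side at a log2 ratio of 1.19. The axonal adhesion gene Cntn2 had a log2 ratio of 1.62. Gap43, a growth cone gene, was 2.86-fold lower (2.76 to 2.97) and the neurofilament gene Nefl 2.62-fold lower (2.35 to 2.94). Interneuron genes had a median of 0.15 (percentile 68.1, and 0.27 at percentile 97.1 after the length correction), with 2 higher and 2 lower of 17. The transcription factors Sp8 and Dlx2 were 2.80-fold (2.42 to 3.25) and 2.66-fold (2.47 to 2.86) higher, and the neuropeptide gene Npy was 3.74-fold lower (2.87 to 4.93). Sst, another neuropeptide gene, had a log2 ratio of -1.15. Cajal-Retzius genes, of the early neurons under the meninges, had a median of -0.53 (percentile 0.40), with Trp73 2.93-fold (2.46 to 3.50) and Calb2 2.05-fold (1.81 to 2.33) lower. The meningeal list moved the same way, with its median of -3.78. Oligodendrocyte precursor genes had a median of -0.09. Of 6 measured, Pdgfra was the 1 lower (2.38-fold, 2.05 to 2.77) and 5 lay between, with Olig1 at a log2 ratio of 0.23. That list's median was 0.23 with a minimum of 20 CPM.

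Cell cycle genes were slightly higher as sets. S phase genes had a median of 0.25 (percentile 99.8) and G2 and M phase genes one of 0.31 (percentile 99.99), with 0 of 41 and 0 of 52 past 2-fold. Nasp and Cbx5, the most abundant member of each, had log2 ratios of 0.05 and 0.23. Among signalling pathways, Hedgehog genes had a median of 0.38 (percentile 99.3, and 95.03 after the length correction), with Cdon at 0.59. Notch and Wnt lists had medians of -0.08 and 0.00, inside the random range, and the Wnt median was -0.10 with library totals. Within the Notch list, Heyl was 2.77-fold (2.08 to 3.73) and the endothelial ligand Dll4 2.32-fold (1.73 to 3.17) lower.

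Genes of energy metabolism and translation were lower as sets, mostly by less than 2-fold. Transcripts encoded in mitochondria took 3.37% of reads in the control and 1.89% in the knockdown library. The 11 measured protein-coding ones had a median of -0.67, with mt-Nd3 2.20-fold lower (2.08 to 2.32) and mt-Co3 1.98-fold lower (1.96 to 2.01). Nuclear genes of the respiratory chain had a median of -0.52, with 4 of 69 lower, among them Uqcr11 (2.29-fold, 2.02 to 2.60) and Cox6b1 (2.04-fold, 1.91 to 2.18). Cytosolic ribosomal protein genes had a median of -0.33, with 4 lower and 1 higher of 78. Rps14 was 2.12-fold lower (2.06 to 2.17), whereas Rps7 was 2.74-fold higher (2.59 to 2.89), and pseudogene copies can take reads from this family. Glycolysis and hypoxia genes had a median of -0.26 (percentile 0.32), with Ldha at -0.57 and Pkm at -0.03. Log2 ratios also differed with transcript length and with mean CPM over all measured genes. With genes in 10 bins, the median was -0.25 in the shortest bin and 0.22 in the longest, and likewise -0.25 in the bin of lowest CPM and 0.22 in the highest (-0.19 and 0.18 after the length correction). After the length correction the medians were -0.38 for mitochondrially encoded, -0.24 for respiratory chain and -0.21 for ribosomal protein genes. Replication-dependent histone genes, whose mRNAs mostly lack a poly(A) tail, were thinly measured (5 genes, median -0.15), with Hist1h2ap 2.93-fold lower (2.46 to 3.52) and Hist1h1c at a log2 ratio of 1.44. The histone median was 0.09 with no CPM minimum and 0.76 with a minimum of 20 CPM.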

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

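Counts of higher and lower genes depended mainly on the CPM minimum and the fold threshold, and the Rbm3 ratio on the scaling. No replicate could be left out since each group had 1 library. Genes past 2-fold numbered 506 higher and 1384 lower with no CPM minimum, 429 and 1176 at a mean of at least 1 CPM, and 143 and 153 at 20 CPM, against 259 and 547 at 5 CPM. The share that was higher went from 32.1% to 48.3% at 20 CPM, so part of the excess of lower genes lay among genes of low abundance. A 1.5-fold threshold gave 1108 higher and 1504 lower, and a 4-fold threshold 21 and 109. The log2 ratio of Rbm3 was -0.36 with library totals and -0.34 with upper-quartile factors, outside the counting interval of the main value in size but of the same sign. That of Yap1 kept its sign in each alternative (-1.15 to -0.97) but was -0.98 with median-of-ratios scaling and -0.97 with a pseudocount of 2 CPM, short of the 2-fold line. Between 16 and 19 gene lists fell outside the central 95% of random lists over the alternatives, against 18, and with the length correction, chosen after seeing the data, Hippo and Hedgehog genes no longer did. Of 931 values of named genes under alternatives (Rbm3 and Yap1 included), 749 lay within the range spanned by the main value and its counting interval. Of 300 list medians, 237 did, and none of the lists outside the random range changed sign. The authors' calls rested on the preset dispersion: their test gave 2157 genes at a dispersion of 0.04 and 786 at 0.16, against 1231 at 0.1. No paired analysis was possible because each group has a single library. Depth limits genes with few reads most, since 3 reads correspond to 0.163 CPM in the control and 0.185 CPM in the knockdown library.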

Other observations

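Tests were chosen after the results were seen, except for 2: the second meningeal and choroid plexus lists taken as a pair, and the list of blood cell genes. For those 2 the bounds were written beforehand, but the criterion used to read them was altered once their values were known, as given with each.

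A few genes outside the fixed lists were picked after their values were seen and stand for no group. Sox11 had 3201 reads in the control and 10351 in the knockdown library (log2 ratio 1.88), Pou3f3 had 4507 and 12193 (1.62), Pou3f1 had 720 and 2154 (1.75) and Cux2 had 1866 and 3992 (1.28). Unc5d, a guidance receptor of migrating upper-layer neurons, had 808 and 2447 reads (1.77). Rorb and Lmo4, looked up with them, were at 0.22 and -0.25. A second list of interferon-inducible genes had a median of 0.76 over 10 measured genes, with the class I antigen genes H2-D1 at 1.24 (974 and 2036 reads) and B2m at 1.08.

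The lower meningeal and choroid plexus genes have as a candidate explanation tissue carried into the control library despite the sort for GFP, and a second list of meningeal genes, with a median of -1.45 over 14 measured genes, was in line with that for meninges. For the pair of second lists, a higher median above -0.5 had been set beforehand as evidence against carry-over, and the choroid plexus median of -0.43 over 6 measured genes met that bound. Under that reading choroid plexus carry-over is argued against. A criterion over all listed genes, added after this value was seen, leaves it open. It was added because 7 of 13 genes fell under the CPM minimum, and Igfbp2 (3713 and 2840 reads) and Slc29a4 (2324 and 2145) were abundant in both libraries. Of the 13 listed genes, 12 had a log2 ratio below 0, and the median over the 13 was -1.39. A uniform dilution by all other cell types is argued against by a range of 3.90 log2 units between 5 list medians, and scaling by a meningeal median of at least 3.76 in size under 3 other scalings. The libraries differed in their mix of embryo sexes, since Eif2s3y, Ddx3y and Kdm5d had reads in the control and 0 in the knockdown library. Whether that difference or an effect of the Rbm3 plasmid lowered the meningeal and choroid plexus genes stays open and untested. Plasmid, embryos and sort differ together between the libraries.

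For the higher immediate early and interferon genes, cell types and handling may both matter. By a bound set after the values were seen, a uniform gain of microglia is argued against for the immediate early genes. Their median lay 1.46 above that of microglial genes (interquartile range 0.82). Microglial genes were split, however, with Lyz2 3.68-fold and Ptprc 3.66-fold higher and Mrc1 5.25-fold lower (3 higher, 1 lower, 8 between). A gain of some of these cells thus stays open. For the interferon genes more microglia stays open as well: their first list lay 1.18 above the microglial median but the second 0.64. For a list of blood neutrophil and monocyte genes, a median of at most 0 had been set beforehand as evidence against such cells. The median of -0.16 met that bound, but it rests on 2 measured genes, Lcp1 and Coro1a (1591 and 1264 reads), abundant in both libraries. A criterion over all 12 listed genes was therefore added after the value was seen. Of the 12, 10 had a log2 ratio above 0 and 2 below, with a median of 1.07, mostly at low counts. That leaves a trace of blood cells open for the interferon genes. The sort for GFP should leave out such cells and microglia, yet the globin gene Hbb-bs had 3463 reads in the control and 734 in the knockdown library. As the source of Fos, Fosb and Egr1 reads, neutrophils are argued against, since the higher of S100a8 and S100a9, abundant neutrophil transcripts, reached 1.10% of the CPM that Fos gained. Both transcripts were nonetheless higher in the knockdown library, at low levels. S100a8 had 0.651 CPM in the control and 2.04 CPM in the knockdown library, and S100a9 had 0.325 and 2.72 CPM. Stress of dissociation or sorting stays open, because a heat shock median of -0.0093 excludes no such stress, and so does a response to the knockdown plasmid, which the design cannot separate from handling.

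The lower Yap1 level may have sources other than regulation by Rbm3, whose own level differed by less than that of Yap1. The trend with transcript length is argued against, since the length-corrected Yap1 log2 ratio was -1.15. A smaller share of radial glia stays open: their median of -0.58 is in the same direction and smaller. Yap1 reads from vessel or meningeal cells in the control library stay open as well, because no library of those cells gives their Yap1 level. The sort should leave such cells out, yet the meningeal gene Col1a2 had 3244 reads in the control library. The Hippo list median of 0.29 cannot decide it either, since it mixes genes of both directions. An effect of Rbm3 knockdown on Yap1 stays open beside these, untested with 1 library per group.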
